A study of Rattus norvegicus with 8 samples.

How the data were processed

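Gene expression was measured on 8 Agilent 2-colour rat arrays. RNA labelled as from castrated adult male Wistar rats served as the control, and RNA from castrated rats given a single subcutaneous dose of 4 mg/kg testosterone propionate in corn oil, 8 h or 24 h earlier, was hybridised against it on the same array. Each time had 4 arrays, which the labels call biological replicates; whether an array holds the RNA of a single animal or of a pool, whether the controls received oil, and whether both times share control RNA are not given in the sources used here. The series title names muscle atrophy as its subject, and the labels do not name the muscle. At 8 h the treated RNA carried Cy3 in replicates 1 and 2 and Cy5 in replicates 3 and 4; at 24 h it carried Cy5 in replicates 1 and 2 and Cy3 in replicates 3 and 4. If a dye-swapped pair repeated the same extracts, the p-values would be too small. The array records placed the 4 arrays of each time on 1 slide of its own, so time and slide cannot be told apart.

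Total RNA was extracted with Trizol and labelled by a Quick Amp kit, per the labels' protocols. The scans were read with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. Per the file headers, the deposited mean spot signals and median local backgrounds are linear intensities with no normalization, and the processed signals are intensities after spatial background correction and lowess dye normalization. The deposited LogRatio column is the log10 ratio of red (Cy5) over green (Cy3), per the file headers. The deposited table of authors' values holds log2 ratios whose scale, centring and direction are not stated. Over all gene spots it matched the log2 ratio of the processed signals, turned to treated over control by the dyes in the labels, with a largest difference of 1.4e-05; no centring had been added, and the column medians ran from -0.144 to 0.0896. It matched the LogRatio column exactly only where that was not 0: Feature Extraction sets the ratio to 0 on between 22.8% and 31.6% of spots, and over all spots the correlation was between 0.966 and 0.996. The authors' values were therefore an alternative and gave the same numbers as the processed signals.

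Mean signals were corrected with the median local background by normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3). Control spots and spots with outlier flags (between 731 and 927 of 42877 gene spots per array) were left out after background correction, and saturated spots were kept. Each log2 ratio was turned to treated over control, spots of a probe were averaged, and a probe was kept if it was well above background on at least 3 of the 4 arrays in at least 1 of the 4 RNA groups (control or treated, at either time). This kept 12074 of 30367 probes. The brightest kept probe stood for a gene, which left 10873 genes, 1077 of them with more than 1 kept probe. At 24 h no other kept probe of a named gene had the opposite sign; at 8 h Aqp4, Mrtfa, Rps19, Sqstm1, Srm and Tuba1b each had such a probe. Other probes could differ much in size: at 24 h the other probe of Mrtfa stood at 0.21, of Mettl7a at -0.17, of Gabarapl1 at -0.21 and of Sqstm1 at -0.08. Those of Aqp4 stood at -0.64 and -0.50. Names came from the reference gene table (assembly GRCr8, used for names only) through the array's accessions for 18377 probes and through the file's symbol for 2689; 138 probes kept a file symbol that the table does not hold, and 9163 had no symbol. Among the genes kept, 7086 had a symbol. Positions are those of the array files, on rn4; no genome was used, so exons and untranslated regions are not given.

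A linear model with a coefficient for each time and a probe-specific dye coefficient was fitted to all 8 arrays with lmFit and eBayes. Each time's coefficient was tested against 0 and the 2 times against each other, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A total of 39 gene lists was fixed before the data were examined, as were the samples, the tests of genes at each time and between times, the tests of lists at each time and the rule for named genes. The 34 lists with at least 5 measured genes were tested with cameraPR (preset correlation 0.01), and with an estimated correlation and with fry as alternatives. Named genes, ranked at each time and between times only among genes with a symbol in the array file, were the 10 that rose and the 10 that fell most at each time among those past the threshold with the same sign on all arrays (the 5 with the smallest p if none passed in a direction), 16 genes fixed in advance (not all of them are reported here), up to 4 members of each list that passed or held a passing member, and the 10 genes with the smallest adjusted p for the difference between times. Where a gene was not well above background on any array of a group, the fold is a bound: the brighter group's mean against the dim group's mean, with each dim value raised to the lowest signal well above background on its array.

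The share of spots well above background was 34.8% to 41.8% in the control channels and 37.1% to 48.9% in the treated channels. Median spot signals of 45.7 to 66.5 stood over local backgrounds of 36 to 40, and at most 36 spots were saturated in a channel. The number of arrays limits the precision. Data were simulated for the 24 h comparison (10873 genes), with noise drawn independently for each gene at its estimated SD. On these the steps recovered 27 of 49 genes changed by 0.5 on the log2 scale and all genes changed by 1 (52), 1.5 (49) or 2 (50). Estimates were 0.912 to 0.958 of the true change, and 6.51% of the 215 calls were false. No gene was called in the unchanged 8 h comparison, and of the lists only the planted list was called at 24 h. As the simulated noise was not correlated between genes, this cannot tell how often real lists of correlated genes are called falsely. Each gene had the same simulated SD on all arrays and no dye effect of its own. On the real arrays the SD of log2 ratios over genes ranged from 0.18 to 0.444, so the recovery on them may be lower.

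Alternatives covered the processed signals, the authors' values, no background correction, median centring in place of loess, an added Aquantile step, both directions of the filter on dim probes, all kept probes averaged, outlier spots kept, no dye coefficient, each time fitted alone, array weights, dye-swapped pairs or replicate numbers as blocks, other thresholds and each array left out. Lists for the difference between times and their alternatives were added after the data had been seen.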

Results

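The arrays compared RNA of castrated rats given testosterone propionate, an injectable androgen ester, with RNA of castrated controls, 8 h and 24 h after a single dose. There were 4 arrays at each time and each array carried a treated and a control sample, so every value is a log2 ratio of treated over control within an array. Of the 10873 genes measured, 766 passed the threshold at 24 h (450 higher, 316 lower) and 3 at 8 h.

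At 24 h, a muscle ubiquitin ligase had the largest fall among the named genes and a growth factor the largest rise. Fbxo32, which encodes the ligase atrogin-1, fell by 2.48 on the log2 scale (SD 0.48, n = 4 arrays, adjusted p = 0.00014), a level 5.57-fold lower in treated muscle. Trim63, the ligase MuRF1, fell by 0.68 (SD 0.27, adjusted p = 0.0205). Igf1, the growth factor, rose by 1.75 (SD 0.23, adjusted p = 9.81e-05), or 3.36-fold, and Igfbp3, which binds it, fell by 1.84 (SD 0.37, adjusted p = 4.12e-05). Collagen transcripts rose as well, with Col1a1 higher by 1.54 (SD 0.29, adjusted p = 0.00213) and Col3a1 higher by 1.48 (SD 0.40, adjusted p = 0.00391). All 4 arrays showed the direction of each of these changes.

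Among the other genes with the largest falls were Mettl7a at -2.02 (SD 0.10), Ucp3, a mitochondrial uncoupling protein, at -1.97 (SD 0.19), and Klhl38 at -1.94 (SD 0.45). Pik3ip1, an inhibitor of phosphoinositide 3-kinase, stood at -1.80 (SD 0.36), Lmod2, a thin filament protein, at -1.68 (SD 0.75), and the chemokine Cxcl14 at -1.57 (SD 0.22). Asb2, a ubiquitin ligase subunit, stood at -1.46 (SD 0.62) and Aqp4, a water channel of muscle fibres, at -1.40 (SD 0.49). The largest rises besides Igf1 and the collagens were those of G0s2, an inhibitor of lipolysis, at 1.48 (SD 1.02), and Mrtfa, a coactivator of serum response factor, at 1.44 (SD 0.37). Amd1, which makes the aminopropyl donor of polyamine synthesis, rose by 1.42 (SD 0.38), Spns2, a sphingosine 1-phosphate transporter, by 1.39 (SD 0.22), and Myh1, a fast myosin heavy chain, by 1.33 (SD 0.37). Ccdc80, a secreted matrix protein, rose by 1.31 (SD 0.14) and Dpep1, a dipeptidase, by 1.29 (SD 0.39). Each had an adjusted p of at most 0.022, that of Myh1, and kept its sign on all 4 arrays. The probes of close paralogues, such as those of the myosin heavy chains, can share signal, which was not tested.

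On rn4 the Fbxo32 probe lies on chromosome 7 between 94921822 and 94932899, and the Igf1 probe on chromosome 7 at 24604715 to 24604774. The probes of Amd1 and Spns2 lie on chromosome 20 at 44452568 to 44452627 and on chromosome 10 at 59335805 to 59335864. The Col1a1 probe lies on chromosome 10 at 83639260 to 83639319 and the Odc1 probe on chromosome 6 at 41315531 to 41315590.

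**Figure D1:**
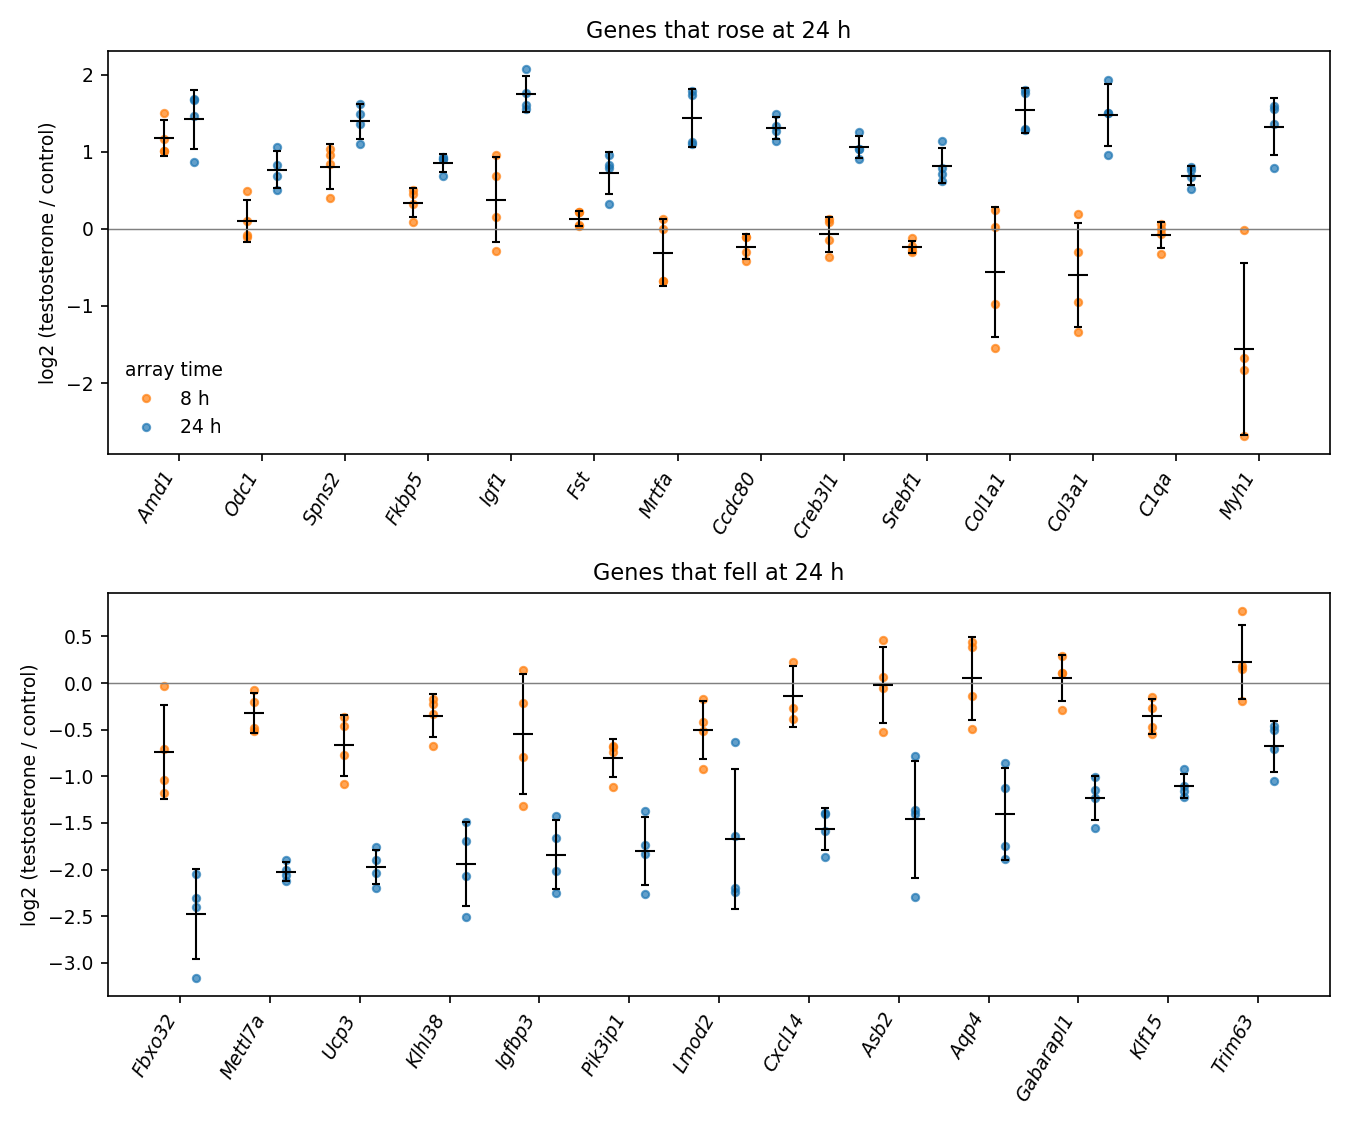
Log2 ratios of treated over control (y axis) for named genes (x axis) on each of the 4 arrays (3 for Cxcl14 at 8 h) at 8 h (orange points) and 24 h (blue points), with the mean as a dash and the SD as an error bar. Amd1 lies near 1.17 at 8 h and 1.42 at 24 h, whereas Fbxo32 lies near -0.74 at 8 h and -2.48 at 24 h.

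Of the genes fixed in advance, Fkbp5, a chaperone induced by steroid receptors, rose by 0.86 (SD 0.11, adjusted p = 0.000387). Odc1, the first enzyme of polyamine synthesis, was at least 1.70-fold higher (adjusted p = 0.00219), a bound because it was not well above background in any control sample of 24 h. Myog, a myogenic transcription factor, rose by 0.37 (SD 0.26, adjusted p = 0.0398). Smox (-0.05), Sat1 (-0.04), Mstn (-0.00), Myod1 (0.13), Zbtb16 (-0.20) and Myh3 (-0.05) did not pass. No probe carried the name Foxo1, and Myc was well above background on 2 of 4 treated arrays and 0 control arrays at each time, too few to be tested.

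Ubiquitin ligases and atrophy genes shifted down at 24 h: of 21 measured, 7 fell, 1 rose and 13 did not pass, against 8 that fell and 1 that rose adjusted over the list alone. Asb2, Ctsl (-0.89), a lysosomal protease, and Fbxo31 (-0.52) were among those that fell, and the metallothionein Mt2A (0.62) rose. The list passed its test (adjusted p = 9.99e-05) but not with an estimated correlation (adjusted p = 0.0807 with an estimated correlation). Autophagy and lysosome genes also shifted down: 6 of 19 fell, 0 rose and 13 did not pass, with 7 lower and 1 higher adjusted over the list alone. Gabarapl1, a protein of the autophagosome membrane, fell by 1.23 (SD 0.23), Ulk1, the kinase that starts autophagy, by 1.00 (SD 0.21), and the cargo receptor Sqstm1 by 0.55 (SD 0.48). This list passed under either correlation (adjusted p = 2.39e-05, and adjusted p = 3.18e-05 with an estimated correlation).

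Extracellular matrix genes and macrophage markers were higher together at 24 h. Of 29 matrix genes 8 rose, 0 fell and 21 did not pass, and 14 were higher and 2 lower adjusted over the list alone; Col1a2 rose by 1.13 (SD 0.08) and Col5a2 by 0.88 (SD 0.24). Of 14 macrophage and monocyte markers 5 rose and 9 did not pass, and 7 were higher adjusted over the list alone; the complement genes C1qa and C1qc rose by 0.69 (SD 0.13) and 0.43 (SD 0.12), and the scavenger receptor Cd163 by 0.50 (SD 0.09). The matrix list passed its test at adjusted p = 1.44e-05 and the macrophage list at adjusted p = 4.94e-05. Neither call held when the correlation was estimated, with adjusted p = 0.146 with an estimated correlation for the matrix and adjusted p = 0.204 with an estimated correlation for the macrophage markers.

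Genes of protein folding and lipid synthesis shifted up at 24 h. In the heat shock and unfolded protein response list 7 of 26 rose, 1 fell and 18 did not pass (12 higher and 2 lower adjusted over the list alone). The cochaperone Bag3 rose by 0.88 (SD 0.21), the endoplasmic reticulum chaperones Hspa5 and Calr by 0.74 (SD 0.12) and 0.52 (SD 0.07), and Chac1, a glutathione-degrading enzyme, fell by 0.45 (SD 0.10). The list passed at adjusted p = 2.39e-05, and at adjusted p = 0.0243 with an estimated correlation. Of 15 sterol and fatty acid synthesis genes 4 rose and 11 did not pass, and 7 were higher adjusted over the list alone; Srebf1, a transcription factor of lipid synthesis, rose by 0.82 (SD 0.23), Acly by 0.72 (SD 0.19) and Hmgcs1 by 0.50 (SD 0.31). That list passed at adjusted p = 0.00202, but stood at adjusted p = 0.0807 with an estimated correlation.

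Of 15 androgen-responsive genes 5 rose, 2 fell and 8 did not pass, with 6 higher and 2 lower adjusted over the list alone. Igf1, Fkbp5 and Odc1 rose, and the kinase Sgk1 (-0.49, SD 0.20) was among those that fell. The list passed at adjusted p = 0.0109, but stood at adjusted p = 0.103 with an estimated correlation, and its call was also lost without the 24 h array of replicate 2 or of replicate 3, under median centring and with a strict filter on dim probes (adjusted p = 0.339, the highest of these). Among 18 adult fast contractile genes 3 fell, 1 rose and 14 did not pass, and 8 were lower and 1 higher adjusted over the list alone. The myosin light chain kinase Mylk2 fell by 0.83 (SD 0.06), Actn3 by 0.55 (SD 0.21) and Acta1 by 0.44 (SD 0.15), whereas Myh1 rose. This list passed at adjusted p = 9.99e-05, with adjusted p = 0.324 with an estimated correlation and 0.289 under median centring. Of 33 oxidative phosphorylation and TCA cycle genes 1 fell, Cox4i1 (-0.55, SD 0.21), and 32 did not pass, as adjusted over the list alone; the list lay lower as a set (median -0.11, adjusted p = 0.0109, and adjusted p = 0.00951 with an estimated correlation) but not under median centring (adjusted p = 0.801) or from the processed signals. Its array medians split by dye, at -0.142 and -0.244 with the treated RNA in Cy5 and 0.024 and 0.0369 with it in Cy3, so 2 of 4 arrays lay below 0.

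**Figure D2:**
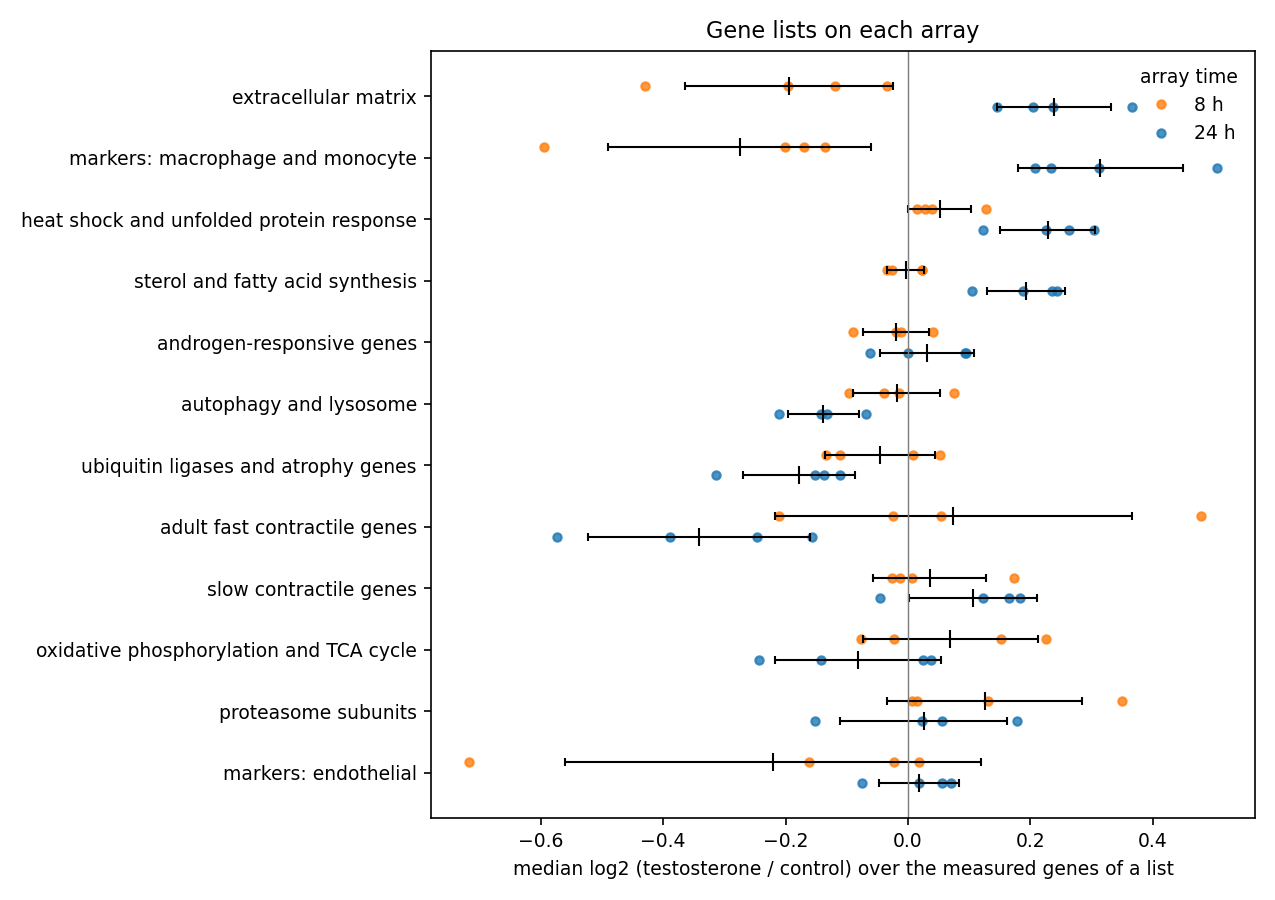
Median log2 ratio of treated over control (x axis) over the measured genes of 12 lists (y axis) on each array at 8 h (orange) and 24 h (blue), with the mean as a tick and the SD as an error bar. The macrophage and monocyte markers lie between -0.594 and -0.136 on the 8 h arrays and are above 0 on the 24 h arrays.

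Of the 8 ways to turn treated and control on the 24 h arrays, 3, the labelled one included, called as many lists as the 9 that passed. Chance was thus not excluded for the number of lists. The other 25 lists tested did not pass at 24 h. Their adjusted p was 0.0589 for angiogenesis, 0.061 for glycolysis, 0.0656 for adipocyte markers, and 0.0915 each for polyamine metabolism, fatty acid oxidation and fibroblast markers. It was 0.17 for glucocorticoid and FoxO targets, 0.427 for cytosolic ribosomal proteins, 0.452 for denervation and neuromuscular junction genes, 0.477 for developmental and cardiac contractile genes, 0.541 for slow contractile genes and 0.758 for immediate early genes. It was 0.8291 each for the myostatin, activin and BMP pathway and for smooth muscle and pericyte markers, and 0.833 each for the IGF1, PI3K and mTOR pathway and for translation factors and aminoacyl-tRNA synthetases. It was 0.885 for the circadian clock, 0.902 each for proteasome subunits and amino acid transporters, 0.96 for the cell cycle, 0.963 for oxidative stress genes and 0.983 for Schwann cell and nerve markers. Myogenic regulators, ribosome biogenesis and endothelial markers each had an adjusted p of 0.999. Neutrophil, lymphocyte and mast cell markers (2 measured each), erythrocyte markers (3) and epithelium and male accessory gland markers (1) had too few measured genes for a test, and none of these genes passed at either time. The erythrocyte markers varied widely between arrays. Their array medians for replicates 1 to 4 were -1.42, 0.385, -2.18 and -0.337 at 8 h, and 0.0927, -0.0385, 1.58 and -0.307 at 24 h.

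The 24 h count depended on the arrays and the scaling. It was 191, 361, 331 and 379 without the 24 h arrays of replicates 1, 2, 3 and 4, 510 without the 8 h array of replicate 3 and 1240 without the 8 h array of replicate 1. Median centring in place of loess moved the median of all genes to 0.155 at 24 h, and with it 379 genes were higher and 18 lower, so 95.5% of calls were rises against 58.7% with loess.

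At 8 h, Amd1 rose by 1.17 (SD 0.23, n = 4) and Spns2 by 0.81 (SD 0.29, n = 4), each at adjusted p = 0.0282. The third gene past the threshold, a transcript without a symbol (ENSRNOT00000043148), fell by 0.53 (SD 0.17, adjusted p = 0.0282). All 3 changed in the same direction at 24 h. The named genes with the smallest p among those lower at 8 h did not pass: Pfkfb3, a regulator of glycolysis, at -0.77 (SD 0.42), Pik3ip1 at -0.80 (SD 0.21), Ucp3 at -0.67 (SD 0.33), Zbtb38 at -0.69 (SD 0.39) and Myh1 at -1.55 (SD 1.11). Fbxo32 stood at -0.74 (SD 0.51, adjusted p = 0.264) and Igf1 at 0.38 (SD 0.55, adjusted p = 0.265).

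Odc1 was not well above background in any control sample of 8 h and in 2 of 4 treated samples (at least 1.07-fold, adjusted p = 0.592). The other genes fixed in advance had log2 ratios at 8 h of 0.34 for Fkbp5, 0.23 for Trim63, -0.03 for Myog, -0.16 for Smox, 0.05 for Sat1, 0.19 for Mstn, 0.25 for Myod1, 0.01 for Zbtb16 and -0.15 for Myh3, and did not pass.

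Among gene lists at 8 h, macrophage and monocyte markers and extracellular matrix genes lay lower, and proteasome subunits and oxidative phosphorylation and TCA cycle genes higher, though no member of these 4 lists passed alone. The macrophage markers had a median of -0.31 over 14 genes (6 lower adjusted over the list alone) and adjusted p = 5.59e-05, or adjusted p = 0.544 with an estimated correlation. The 29 matrix genes had a median of -0.13 (0 passing adjusted over the list alone) and adjusted p = 0.0014, or adjusted p = 0.544 with an estimated correlation. The call was lost with array weights and without the 8 h array of replicate 2 (adjusted p = 0.299, the highest of these). The 34 proteasome subunits had a median of 0.10 (0 passing adjusted over the list alone) and adjusted p = 0.0014, or adjusted p = 0.754 with an estimated correlation. That call was lost with array weights and without the 8 h array of replicate 1 (adjusted p = 0.369, the highest of these). The 33 oxidative phosphorylation genes had a median of 0.08 (0 passing adjusted over the list alone) and adjusted p = 0.0156. This list held at adjusted p = 0.0118 with an estimated correlation, but not without the array of replicate 2 or of replicate 4, or without a dye coefficient. Its array medians were 0.225 and 0.152 with the treated RNA in Cy3 and -0.0775 and -0.0233 with it in Cy5, so 2 of 4 arrays lay above 0. The other 30 lists had adjusted p from 0.0637 (heat shock) to 0.919. Among these, endothelial (median -0.10, adjusted p = 0.154), smooth muscle and pericyte (-0.11, adjusted p = 0.116) and fibroblast markers (-0.16, adjusted p = 0.234) also lay below 0. The array of replicate 1 stood apart: on it the SD of log2 ratios over genes was 0.444, against 0.18 to 0.201 on the others.

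At 8 h 1862 genes had an unadjusted p under 0.05, where 544 are expected by chance. The count of 3 rested on single arrays: it was 1223 (384 higher, 839 lower, including all 3) without the 8 h array of replicate 2, 0, 0 and 1 (a gene outside the 3) without those of replicates 1, 3 and 4, and 0 or 1 without an array of 24 h. The array of replicate 2 correlated across genes with that of replicate 1 at 0.282 and with those of replicates 3 and 4 at -0.126 and -0.0354. With treated and control turned on that array, 1 list was called at 8 h instead of 4, and without it 2 were.

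Between the times, 141 genes responded differently, 79 with a higher log2 ratio at 24 h and 62 with a lower. Among genes with a symbol, Mrtfa differed most clearly, at -0.31 (SD 0.43) at 8 h and 1.44 (SD 0.37) at 24 h, a difference of 1.74 (adjusted p = 3.29e-05), though its other kept probe stood at 0.01 at 8 h and 0.21 at 24 h. Mettl7a (a difference of -1.70, adjusted p = 0.000445), Ccdc80 (1.54, adjusted p = 0.000547), the phospholipase Plcd4 (1.19), Tjap1 (1.20) and Gabarapl1 (-1.29) followed, the last 3 at an adjusted p of at most 0.00207. The other kept probes of Mettl7a and Gabarapl1 also gave smaller values at 24 h, -0.17 against -2.02 and -0.21 against -1.23. The tubulins Tuba1a (1.05) and Tuba1b (0.95), the matrix regulator Creb3l1 (1.13) and Srebf1 (1.05) completed the 10 genes with a symbol and the smallest p, at an adjusted p of at most 0.00727. Amd1 (0.25, adjusted p = 0.559) and Spns2 (0.59, adjusted p = 0.0504) did not differ past the threshold.

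Of the 34 lists, 11 differed between the times. Macrophage markers (median difference 0.73, adjusted p = 3.35e-11), matrix genes (0.36, adjusted p = 5.15e-11) and fibroblast markers (0.13, adjusted p = 0.0104) were higher at 24 h, with 4 of 14, 5 of 29 and 3 of 11 members past the threshold (9, 15 and 5 higher and 0, 1 and 1 lower adjusted over the list alone). Oxidative phosphorylation genes (-0.21, adjusted p = 3.13e-05; 0 of 33 members, as adjusted over the list alone, with arrays of both signs, split by dye, at each time) and autophagy genes (-0.11, adjusted p = 0.000217; 2 of 19 members, 6 lower and 1 higher adjusted over the list alone) were lower. These 5 also passed when the correlation was estimated, at no more than adjusted p = 0.0259 with an estimated correlation. Fast contractile genes (-0.40, adjusted p = 6.44e-05, and adjusted p = 0.339 with an estimated correlation), atrophy genes (-0.20, adjusted p = 0.00119, and adjusted p = 0.145 with an estimated correlation) and proteasome subunits (-0.15, adjusted p = 0.0189, and adjusted p = 0.637 with an estimated correlation) were lower with the preset correlation but not with the estimated correlation or fry. Of their members Myh1 was higher and Fbxo32 lower past the threshold, and adjusted over the list alone 7 of 18 fast contractile genes were lower and 1 higher, 4 of 21 atrophy genes lower and 1 higher, and 0 of 34 proteasome subunits passed. Sterol synthesis genes (0.18, adjusted p = 0.00565, and adjusted p = 0.103 with an estimated correlation), heat shock genes (0.24, adjusted p = 0.0387, and adjusted p = 0.339 with an estimated correlation) and adipocyte markers (0.37, adjusted p = 0.0311, and adjusted p = 0.443 with an estimated correlation) were higher with the preset but not with the estimated correlation; with fry the sterol list passed (adjusted p = 0.0352), the heat shock and adipocyte lists did not, and the matrix list did not either (adjusted p = 0.0566). Srebf1 and the lipid carrier Fabp4 (0.60) were their members past the threshold, and adjusted over the list alone 2 of 15 sterol genes were higher, 5 of 26 heat shock genes higher and 2 lower, and 4 of 8 adipocyte markers higher and 1 lower. The calls for fibroblast markers and sterol synthesis were lost in 1 of 22 alternatives, without the 8 h array of replicate 2 (adjusted p = 0.0648 each). Those for heat shock, proteasome and adipocyte genes were lost in 9, 7 and 5 of 22. Among these were leaving out the 8 h arrays of replicates 2, 3 and 4 or the 24 h arrays of replicates 1 and 4 for heat shock, the 8 h array of replicate 1 or the 24 h arrays of replicates 2 and 3 for the proteasome, and the 8 h arrays of replicates 3 and 4 or the 24 h array of replicate 1 for adipocyte markers.

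Each time lay on 1 slide, so the difference between times cannot be told apart from a difference between slides. The count of 141 was 0 under median centring (limma, 897 genes at an unadjusted p under 0.05), 86 from the processed signals, 596, 57 and 49 without the 8 h arrays of replicates 2, 3 and 4, and 28, 93, 57 and 79 without the 24 h arrays of replicates 1, 2, 3 and 4.

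Across genes, which are not independent replicates, the changes at 8 h and 24 h correlated weakly (Pearson r = 0.162, Spearman rho = 0.186, with a jackknife SE of 0.117 for r). Of the 766 genes past the threshold at 24 h, 457 (59.7%) had the same sign at 8 h. Without the 8 h array of replicate 2 the share was 60.8% and r = 0.184, and with that array turned 59.9% and r = 0.19. Unchanged groups simulated with control RNA shared by replicate number gave r = 0.50 and a covariance of 0.00472, against an observed covariance of 0.00605. Between means of 2 arrays of each time that share no replicate number, r was 0.0859 to 0.207. Between single arrays without a shared number it ran from -0.0784 to 0.316. Under median centring r was 0.386.

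**Figure D3:**
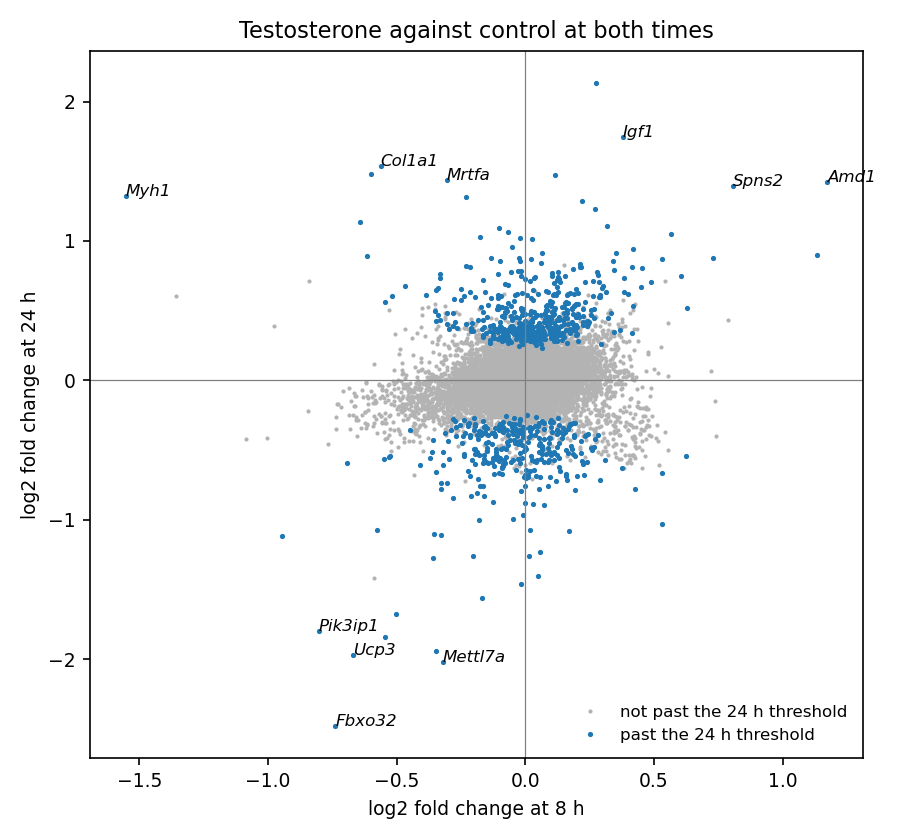
Log2 fold change of treated over control at 8 h (x axis) and 24 h (y axis) for the 10873 genes measured, with the 766 genes past the 24 h threshold in blue and the others in grey. Amd1 and Spns2 lie up at both times, and Fbxo32 reaches -2.48 at 24 h.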

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

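The comparisons of spot noise on both unusual arrays, of exchanged samples on the array of replicate 1, of red over green on the array of replicate 2 and of the other tissue markers at 24 h were chosen after the results had been seen, as were 2 of the 3 gene sets used for the array of replicate 2.

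Macrophage markers and extracellular matrix genes (43 genes) were lower at 8 h (median -0.202) and higher at 24 h (median 0.267). A dye effect alone was excluded for the mean of the 2 lists by the test written in advance. The mean of the 2 list medians was at least 0.115 away from 0, with the same sign, in either dye orientation of each time. At 8 h it was -0.355 with the treated RNA in Cy3 and -0.115 with it in Cy5, over 2 arrays each. A dye contribution to the size of the 8 h fall therefore stays open. The matrix list was not tested alone. Its 8 h array medians were -0.43 and -0.195 with the treated RNA in Cy3, and -0.0352 and -0.12 with it in Cy5. A dye effect on the matrix genes at 8 h thus stays open. At 24 h the 43 genes stood 0.288 (SE 0.0458) above 26 endothelial, smooth muscle, pericyte and Schwann cell markers, whose array medians had a mean of 0.00143. This argues against a lower share of muscle fibres that raised all other tissue alike. The 2 lists had been picked for their change in these data, so part of the gap was built in, and an unequal rise stays open. The 8 h array of replicate 1 alone was excluded, because the median without it was -0.128. A larger share of fat and connective tissue alone at 24 h was not tested and stays open. Adipocyte markers had array medians of 0.495, 0.182, 0.273 and -0.0408, and fibroblast markers of 0.154, 0.101, 0.0312 and -0.0035, and neither list passed. A higher share of fibres at 8 h stays open too, where endothelial (6 of 7 below 0), smooth muscle and pericyte (9 of 11) and fibroblast markers (8 of 11) also lay low without passing. Of the Schwann cell and nerve markers 4 of 8 lay below 0 (median -0.045). The endothelial median was -0.7175 on the array of replicate 1, and 0.0182, -0.0236 and -0.1623 on those of replicates 2, 3 and 4. The slide, with 1 per time, and a response to the hormone of the cells that express the macrophage and matrix genes also stay open.

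Of the 8 h arrays, that of replicate 1 had wider ratios and that of replicate 2 correlated with replicate 1 (0.282) but not with replicates 3 and 4 (-0.126 and -0.0354). For replicate 1, noise between spots (0.873 of the highest SD of another array) and exchanged samples (highest r with another 8 h array 0.374) were excluded, and another share of fibre types (slow minus fast 0.198) stays open. For replicate 2, noise between spots was excluded (0.794). A dye effect on the slide stays open: red over green gave r = 0.282 with replicate 1, which has the same dye orientation and so cannot tell dye from treatment. With replicates 3 and 4 red over green gave r = 0.126 and 0.0354. The test written in advance for exchanged samples on it was met, at r = -0.11 with the 24 h change over 1603 genes called from the 24 h arrays alone, against 0.106, 0.187 and 0.306 for the other 3 arrays. Over 127 genes with larger changes r was 0.172 and over the 300 genes with the smallest p it was -0.0178. As the larger changes were required only after these values had been seen, an exchange stays open and the labelled direction was kept. On this array Amd1 (1.17), Spns2 (0.955), Pik3ip1 (-0.741) and Ucp3 (-0.364), chosen after their values were seen, had the sign of the other 8 h arrays. So did the macrophage (-0.201) and matrix (-0.195) medians. These genes and lists stood out in an 8 h fit that includes this array as labelled, so their signs cannot decide its direction. The glycolysis (0.336) and adipocyte (0.232) medians had the opposite sign, and that of fast contractile genes (0.479) lay far above the others (-0.0254, -0.21 and 0.0535).

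Fast contractile genes were lower at 24 h, and another share of fast and slow fibres in the 2 samples could give this. The median of slow minus fast contractile genes was 0.280, 0.554, 0.756 and 0.201 on the 4 arrays, and as the lowest was 0.201 this stays open.

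Regrouping the arrays tested chance. At 24 h 1 of 8 groupings gave as many genes (766, the highest other 0), and at 8 h 2 of 8 did (3, the highest other 841, from turning the array of replicate 2 alone); with 8 groupings chance cannot be excluded. For the difference between times 1 of 34 groupings gave as many genes as the 141 observed (the highest other 2). This argues against a random split of the arrays. The observed split is also the split by slide, so a difference between slides could give the same result. For lists it was 4 of 8 groupings at 8 h (highest other 10), 3 of 8 at 24 h (highest other 9) and 3 of 34 for the difference (highest other 12), so chance was not excluded.

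A single array stood far from the other 3 in 15 of 348 groups of values, where chance gives about 1 in 20, or 17.4. At 8 h these were Chac1 at 0.178 on the array of replicate 2, and G0s2 at -0.173 and Nrap at -0.323 on that of replicate 3. On the 8 h array of replicate 1 they were Pecam1 at -0.718, Pik3ip1 at -1.11, Psma2 at 1.12, Rpl18 at -0.511, Uqcrfs1 at 0.741, the median of slow contractile genes at 0.173, the median of macrophage markers at -0.594 and the SD over genes at 0.444. At 24 h they were Cox8b at 0.024 and Fkbp5 at 0.687 on the array of replicate 3, and Pecam1 at 0.377 and the median of polyamine metabolism at 0.0848 on that of replicate 4.

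The named genes past the threshold for the difference with a higher log2 ratio at 24 h than at 8 h were Myh1 (2.88), Col1a1 (2.10), Col3a1 (2.08), Col1a2 (1.78), Mrtfa (1.74), Ccdc80 (1.54), Igf1 (1.37), Tjap1 (1.20), Plcd4 (1.19), Creb3l1 (1.13), Dpep1 (1.07), Srebf1 (1.05), Tuba1a (1.05), Col5a2 (1.01), Tuba1b (0.95), Cd163 (0.85), C1qa (0.77), C1qc (0.76), Fcer1g (0.70) and Fabp4 (0.60). Those past it with a lower log2 ratio at 24 h were Fbxo32 (-1.74), Mettl7a (-1.70), Klhl38 (-1.59), Aqp4 (-1.45), Cxcl14 (-1.40), Ucp3 (-1.30), Igfbp3 (-1.29), Gabarapl1 (-1.29), Srxn1 (-1.17), Pik3ip1 (-0.998), Ulk1 (-0.95) and Klf15 (-0.75). The other kept probes of Aqp4 differed less between the times, lying between -0.33 and -0.15 at 8 h and between -0.64 and -0.50 at 24 h. The median differences of the lists were -0.40 for fast contractile genes, -0.21 for oxidative phosphorylation, -0.20 for atrophy genes, -0.15 for proteasome subunits, -0.11 for autophagy, 0.13 for fibroblast markers, 0.18 for sterol synthesis, 0.24 for heat shock, 0.36 for extracellular matrix, 0.37 for adipocyte markers and 0.73 for macrophage markers.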

How the results depend on the processing

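The test of lists for the difference between times and its alternatives were chosen after the results had been seen, and the others before.

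At 8 h 3 genes passed. The count was 1 from the processed signals and from the authors' values, 1 without a dye coefficient and 1 with a log2 change of at least 1 required. It was 0 with each time fitted alone and 0 under median centring (limma, 1883 genes at an unadjusted p under 0.05). With dye-swapped pairs as blocks it was 16 for pairs 1 and 3, 2 and 4, and 3 for pairs 1 and 4, 2 and 3. The correlation within pairs was -0.217 for the first pairing and 0.0457 for the second, so the higher count came with a negative correlation. Leaving out an array gave 0 to 1223: 1223 without the 8 h array of replicate 2, 0, 0 and 1 without those of replicates 1, 3 and 4, and 0 or 1 without a 24 h array. Both named 8 h calls, Amd1 and Spns2, were lost in more than 5 of 23 alternatives (other thresholds not counted).

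At 24 h 766 genes passed. The count was 397 under median centring (281 shared), 1603 with each time fitted alone and 1603 with array weights. It was 42 with a log2 change of at least 1 required and 1333 at a threshold of 0.1. With dye-swapped pairs as blocks it was 1378 for pairs 1 and 3, 2 and 4, and 683 for pairs 1 and 4, 2 and 3. Leaving out an array gave 191 (24 h, replicate 1) to 1240 (8 h, replicate 1), with 361, 331 and 379 without the 24 h arrays of replicates 2, 3 and 4 and 510 without the 8 h array of replicate 3. Of 83 named 24 h calls, 38 held in every alternative that measured them (22 or 23 each, other thresholds not counted), 28 were lost in 1 to 5 and 17 in more than 5: Rps19, Mef2d, Actn3, Abcc9, Fcer1g, Idi1, Nfe2l2, Srm, Cebpb, Fbl, Kdr, Acta1, Adm, Gys1, Myog, Rps6kb1 and Sqstm1. Under median centring Abcc9 (0.0172) and Gys1 (0.0762) changed sign.

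The difference between times was 141 genes. It was 86 from the processed signals and from the authors' values, and 0 under median centring (limma, 897 genes at an unadjusted p under 0.05). It was 302 with array weights, 40 with a log2 change of at least 1 required and 460 at a threshold of 0.1. With dye-swapped pairs as blocks it was 559 for pairs 1 and 3, 2 and 4, and 120 for pairs 1 and 4, 2 and 3. Leaving out an array gave 28 (24 h, replicate 1) to 596 (8 h, replicate 2), with 57 and 49 without the 8 h arrays of replicates 3 and 4 and 93, 57 and 79 without the 24 h arrays of replicates 2, 3 and 4. The correlation between times, 0.162, was 0.386 under median centring and 0.105 to 0.252 with an array left out.

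The replicate number did not pair arrays across times: deviations from the group mean correlated at -0.261, 0.173, -0.159 and -0.0795 for numbers 1 to 4. With the number as fixed coefficients the difference was 311 genes (106 higher, 205 lower). In a separate fit with the number as a random block the counts were 3 at 8 h and 800 at 24 h.

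The 4 lists at 8 h were 8 without a filter on dim probes, 1 with an estimated correlation, 0 with fry, 2 without the 8 h array of replicate 2 and at most 6 without another. The 9 lists at 24 h were 3 with an estimated correlation, 6 with fry and 9 to 12 with an array left out. The 11 lists of the difference were 5 with an estimated correlation, 5 with fry and 8 to 12 with an array left out.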

Other observations

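The genes below were chosen by rules fixed in advance, and reading them together was done after the results had been seen.

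At 24 h 3 of 14 polyamine genes rose and 11 did not pass, with 4 higher adjusted over the list alone: Amd1, Odc1 and the spermidine synthase Srm (0.33). Angiogenic factors changed in both directions, with 3 of 10 higher, 2 lower and 5 not passing (5 higher and 2 lower adjusted over the list alone). Vegfa (0.80), Pgf (0.87) and the receptor Kdr (0.36) rose, and the oxygen sensor Egln3 (-0.44) and Adm (-0.35) fell.

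In the growth pathway lists single members passed, while the lists did not pass the test for a shift in 1 direction. In the IGF1, PI3K and mTOR list 3 of 22 rose, 1 fell and 18 did not pass (4 higher and 1 lower adjusted over the list alone): Igf1 and the kinase gene Rps6kb1 (0.41) were among those that rose, and Igfbp3 fell. Fst (0.73), which binds myostatin, was the only 1 of 17 myostatin pathway genes to rise, with 0 that fell, and adjusted over the list alone 1 was higher and 1 lower. Among glucocorticoid and FoxO targets 3 of 23 rose, 3 fell and 17 did not pass (3 higher and 4 lower adjusted over the list alone), with Klf15 (-1.10) and Cebpb (-0.62) lower.

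Of 19 oxidative stress genes 3 rose, 3 fell and 13 did not pass (4 higher and 3 lower adjusted over the list alone). Sod3 (-0.78), Srxn1 (-0.54) and the regulator Nfe2l2 (-0.31) fell. Txnip (0.70) and Gpx1 (0.43) rose, though Txnip did not have the same sign on all 4 arrays. The deacetylase Hdac4 (-0.84), the transcription factor Jun (-0.80), Pes1 (-0.56) and the sarcomere protein Nrap (-0.52) also fell, and Rps6 (0.45) rose.

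Control RNA shared between times could add to the correlation of the 2 responses. Controls simulated as shared by replicate number gave a covariance of 0.00472 against 0.00605 observed, and r = 0.50 against 0.162. As it stays open whether the replicate number pairs arrays across times, this simulation cannot tell how much shared controls added. Under median centring the correlation was 0.386. The slide, with 1 per time, leaves open whether the lower matrix and macrophage values at 8 h belong to the time.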
